A study of Mus musculus with 6 samples.

How the data were processed

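The data are raw read counts per gene for 6 mouse RNA-seq libraries, 3 labelled TNFR2-deficient Treg and 3 labelled TNFR2-positive Treg. Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was captured with oligo-dT beads and fragmented, and libraries were amplified by PCR, with no molecular identifiers described. Per the submitters' processing notes, HISAT2 2.1.0 and the mouse genome build GRCm39 were used. The program that made the deposited counts, its gene annotation, its strand setting and its handling of reads with several positions are not given in the sources used here. The authors deposited whole-number counts without normalization, and the values summed to a different total in each library. The mitochondrial gene mt-Co3 and a nuclear copy of it, Gm28437, had nearly equal counts (166170 and 165390 in TNFR2-deficient library 1), so single values of mitochondrial genes and their copies are uncertain. Every column of counts was matched to its sample by name, and groups and replicate numbers were taken from the sample titles.

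The table held 32377 gene identifiers, of which 30529 were matched to a symbol in the gene name table supplied and 1848 were not. Those without a symbol held 0.495% to 0.596% of the counts and stayed in the tests. For 13 duplicated symbols the identifier with the most counts carries the name. The GENCODE M21 annotation is of an older build, so it served for biotypes and gene lengths only, no coordinates are printed, and 97.8% of the tested genes had a length.

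Genes were filtered with filterByExpr, scaled with TMM and tested with glmQLFit and glmQLFTest of edgeR 4.0.16 in R 4.3.3, with an intercept and the group as the design. P-values were adjusted by the Benjamini-Hochberg method over 17022 genes, with a threshold of 0.05. The common biological coefficient of variation was 7.62%. Levels are TMM-scaled CPM, and ratios for genes with at most 20 counts in the lower group carry exact 95% binomial intervals. On simulated data for this comparison with 16657 genes tested, 200 genes changed by known folds. The test recovered 68% of 50 genes changed 1.5-fold, 82% of those changed 2-fold, 96% at 4-fold and 100% at 8-fold, and 8 unchanged genes, 4.42% of the calls, passed. Far fewer genes changed there than were called in the data (69.3% of those tested). Neither a relation to gene length nor a shift in the mix of cells was simulated, so these rates may not hold for the data.

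The 27 gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule named Tnfrsf1b, Trip13, Hat1 and Foxp3; the 6 genes with the greatest fold change in each direction among those past the threshold with a mean of at least 5 CPM and no overlap between groups, skipping unnamed models, pseudogenes and antigen receptor segments; and the 2 members of each list with the smallest adjusted p. Some genes that the rule names are not reported here. Other genes are said to have been chosen after their values were seen. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and at an estimated one, and with fry, adjusted over the 27 lists. fry asks whether a list's genes move on balance one way, without comparing them with other genes. Of 10 lists past the threshold with the preset correlation, 0 passed with an estimated one, where the smallest adjusted p was 0.0859 and 4 lists had an unadjusted p below 0.05, while fry passed 22. Adjusting p over the list alone gave the same counts for 22 lists and other counts for 5.

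Replicates were compared by chi-square over genes. The statistic per gene was 2.53 to 4.77 between TNFR2-deficient libraries and 2.59 to 20.8 between TNFR2-positive ones. All were above sampling noise, so no library was treated as a copy of another. TNFR2-positive library 1 gave the high values, 15.6 and 20.8 against libraries 2 and 3, with 2.59 between those. Alternatives chosen before the data were examined were DESeq2 1.42.0, limma-voom, RLE, upper-quartile and no scaling beyond library size, other filters, a minimum log2 fold change of 1, the replicate number as a block and leaving out each library. Added after the data were seen were the removal of each library's relation to exonic and intronic gene length by offsets from splines with 4 degrees of freedom, and a fit without genes of B cell, erythroid, platelet and myeloid lists and of mitochondria. The length removal was later also run with an estimated inter-gene correlation for the lists. On simulated unchanged genes with a relation to exonic length, 6453 of 16744 were called without the removal and 0 with it. The simulated relation was a straight line in log2 exonic length, which the splines fit, so this outcome was set by construction. No changed genes and no intronic relation were simulated, so it does not show how the removal treats real changes. Lists of markers of double-positive thymocytes, B cell precursors and thymic epithelium were also added after the data were seen.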

Results

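Gene counts from mouse RNA-seq were compared between 2 groups of 3 libraries, labelled TNFR2-deficient and TNFR2-positive regulatory T (Treg) cells. Treg cells are CD4 T cells that hold other immune cells in check and depend on the transcription factor Foxp3. TNFR2, the product of Tnfrsf1b, is a receptor for tumour necrosis factor that is abundant on Treg cells. The title of the series concerns TRIP13, a remodelling ATPase of spindle checkpoint proteins, and the stability of HAT1, a histone acetyltransferase, and the comparison asks which transcripts differ between Treg cells with and without TNFR2. The labels give neither the tissue, nor a sort or gate, nor whether the deficiency was genetic. Total counts were 23236396, 22465991 and 24038118 in the TNFR2-deficient libraries 1 to 3 and 23587552, 19296082 and 21191655 in the TNFR2-positive libraries 1 to 3. A floor of 3 counts therefore corresponded to 0.125 to 0.155 CPM (counts scaled to the library total), which covers counting error only. Nothing in the labels says that the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical. All values below are TNFR2-deficient over TNFR2-positive, with mean CPM ± SD (n = 3 per group).

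Expression differed widely between the groups. Of 17022 genes tested with edgeR's quasi-likelihood test, 5983 were higher and 5819 lower in the TNFR2-deficient libraries at a Benjamini-Hochberg adjusted p-value below 0.05, together 69.3% of the genes. A change of at least 2-fold was seen for 1364 of the higher and 2299 of the lower genes, and one of at least 8-fold for 217 and 491. The first principal component held 88.1% of the variance and separated the groups. The median log2 fold change (log2FC) over all tested genes was 0.04.

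Tnfrsf1b (ENSMUSG00000028599) was 10.6-fold lower in the TNFR2-deficient libraries, the direction of the label (log2FC = -3.40, SE 0.0738, adjusted p = 1.7e-11). Its levels were 8.30, 7.99 and 7.32 CPM in these libraries and 84.6, 84.2 and 80.2 CPM in the TNFR2-positive ones. Transcripts thus remained detectable in each library. Foxp3 fell further in the same libraries, and TNFR2 is abundant on Treg cells. The fall of Tnfrsf1b therefore does not by itself show a loss of TNFR2 within Treg cells. Trip13 (ENSMUSG00000021569) was 4.78-fold lower (log2FC = -2.26, SE 0.18, adjusted p = 6.99e-07), at 1.36 ± 0.239 against 6.51 ± 0.753 CPM. Hat1 (ENSMUSG00000027018) was 1.19-fold higher (log2FC = 0.25, SE 0.0767, adjusted p = 0.0132), at 50.5 ± 2.31 against 42.6 ± 4.05 CPM. The Hat1 call was lost without TNFR2-deficient replicate 1 (log2FC = 0.20, edgeR adjusted p = 0.0775), with adjusted p between 0.00111 and 0.0775 over the alternatives. Counts of mRNA do not measure the stability of the HAT1 protein. Foxp3 (ENSMUSG00000039521) was 52.2-fold lower (log2FC = -5.71, SE 0.0905, adjusted p = 1.46e-12), at 1.44 ± 0.0974 against 75.5 ± 2.14 CPM, which is 0.692% ± 0.034 against 53.5% ± 0.911 of the level of Trac, the constant region of the T cell receptor alpha chain.

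**Figure D1:**
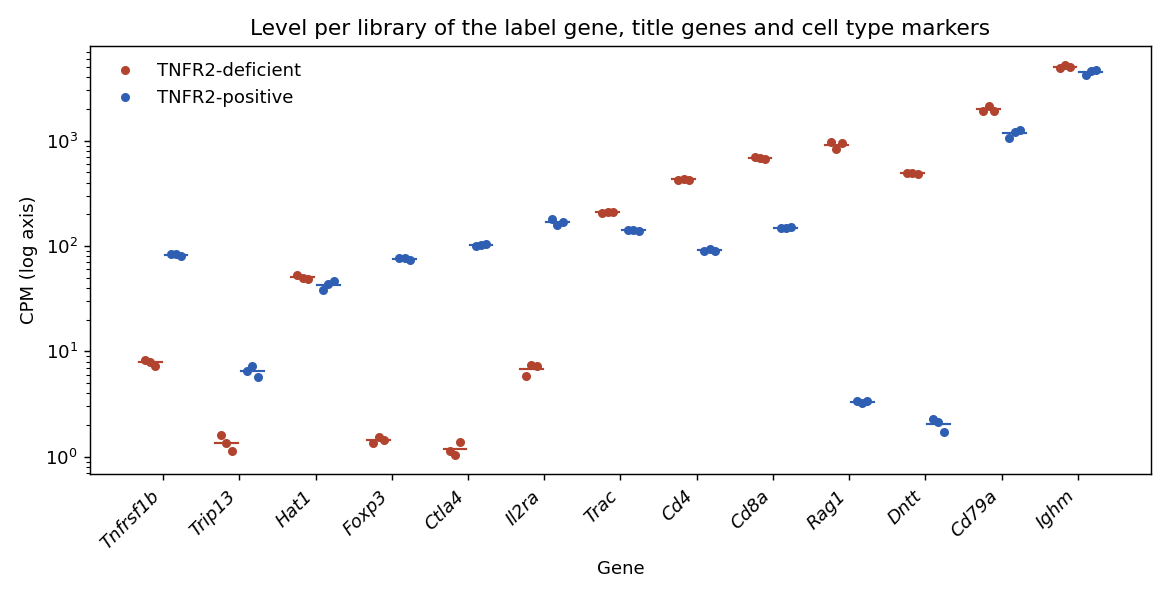
Level per library of 13 genes in CPM on a log axis, with red points for the 3 TNFR2-deficient and blue points for the 3 TNFR2-positive libraries and a line at each group mean. Foxp3 lies near 1.44 CPM in the TNFR2-deficient and near 75.5 CPM in the TNFR2-positive libraries, Rag1 near 917.9 and 3.31 CPM, while Cd79a and Ighm are abundant in both groups.

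Genes that define Treg cells were lower as a group. Of 15 Treg core genes 14 fell and none rose over all genes tested; adjusted over the list alone, 14 fell and 1 rose (median log2FC = -3.68, camera adjusted p = 6.73e-09; adjusted p = 0.0859 with an estimated correlation). Ctla4, an inhibitory receptor that competes with CD28 for its ligands, fell from 102.3 ± 2.63 to 1.18 ± 0.173 CPM (log2FC = -6.43, adjusted p = 1.06e-12). Il2ra, the high-affinity IL-2 receptor chain CD25, fell from 169.1 ± 11.9 to 6.87 ± 0.865 CPM (log2FC = -4.62, adjusted p = 1.5e-11). Capg, singled out because it was the one member not past the threshold, had a log2FC of 0.16 (adjusted p = 0.0658). Of 21 effector Treg and suppressive molecules tested 16 fell and 1 rose, over all genes and adjusted over the list alone (median log2FC = -1.54, camera adjusted p = 1.35e-05; adjusted p = 0.129 with an estimated correlation). Nt5e, the ectoenzyme CD73 that makes adenosine, and Icos, a costimulatory receptor, fell 7.99-fold and 5.42-fold (adjusted p = 6.83e-11 and 1.77e-09). In the same libraries the recombinase gene Rag1 was at 917.9 against 3.31 CPM and globin genes took 1.89% against 0.592% of the counts.

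The genes with the greatest fold changes, among those with a mean of at least 5 CPM, a name and no overlap between the groups, included these Treg genes on the lower side. Beside Ctla4, Foxp3 and Il2ra they were Gprin3 (log2FC = -5.19, adjusted p = 2.45e-06), the receptor Gpr83 (log2FC = -4.91, adjusted p = 5.53e-11) and the transporter-like Mfsd4a (log2FC = -4.80, adjusted p = 8.73e-09). The Gprin3 level of TNFR2-positive library 1 was 20.5 CPM against 8.39 and 7.82 CPM in the other two, and the log2FC was -4.59 without that library. On the higher side stood Syt13, Dgkeos, Tdrd5, Alb, Nwd1 and Arpp21. Arpp21, an RNA-binding protein known from thymocytes and neurons, rose from 0.427 ± 0.119 to 130.9 ± 1.33 CPM (log2FC = 8.26, adjusted p = 4.69e-13). The other 5 had 2 to 5 counts in the whole TNFR2-positive group, so the size of their fold is poorly set. Syt13, a synaptotagmin, had 2 counts there and a ratio of 1148 (95% counting interval 317.6 to 9488). Both counts were in TNFR2-positive library 3, and the fitted log2FC of 9.93 was 12.65 without that library, where the group held 0 counts and the prior count sets the value. The log2FC of Dgkeos, Tdrd5 and Nwd1 was 9.24, 9.15 and 8.42 (adjusted p = 9.85e-11, 3.22e-11 and 3.51e-10), with ratios of 657.1, 609.6 and 373.4 (95% counting intervals 256.4 to 2413, 261 to 1879 and 145.5 to 1372). Without TNFR2-positive replicate 1 these log2FC were 10.41, 9.76 and 7.81, and that of Nwd1 was 9.71 without TNFR2-positive replicate 2. Dgkeos is annotated opposite another gene and its reads cannot be told from that gene's without strand. Alb, the liver gene for serum albumin, was at 63.1, 4.33 and 12.8 CPM in the TNFR2-deficient libraries (log2FC = 8.62, SE 1.47, adjusted p = 0.000252). Its log2FC was 6.98 without TNFR2-deficient replicate 1, and limma-voom gave an adjusted p of 0.0628, with a range up to 0.0628 over the alternatives.

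Several T cell genes were higher while others were lower. Of 20 genes of T cell receptor signalling 9 rose and 7 fell (median log2FC = -0.05, mean 0.30, camera direction up, adjusted p = 0.396, so median and mean differ in sign). With the relation to gene length removed, the median was 0.32, with 12 higher and 6 lower (camera direction up, adjusted p = 0.0368; adjusted p = 0.558 with an estimated correlation). Cd4, the coreceptor for MHC class II, rose from 91.0 ± 1.60 to 428.4 ± 2.84 CPM (log2FC = 2.23, adjusted p = 5.63e-11), and Lat, an adaptor of the receptor, rose by 1.66 on the log2 scale (adjusted p = 2.17e-09). Of 14 cytotoxic and CD8 T cell markers 11 fell and 2 rose (median log2FC = -1.25, camera adjusted p = 0.00303; adjusted p = 0.295 with an estimated correlation). The members that rose were Cd8a and Cd8b1, the chains of the coreceptor for MHC class I, at 686.9 ± 12.3 against 149.6 ± 1.39 CPM and 501.5 ± 16.7 against 106.1 ± 6.44 CPM (log2FC = 2.20 and 2.24, adjusted p = 6.12e-11 and 1.65e-10). Of 17 naive and central memory T cell genes 4 rose and 11 fell (median log2FC = -0.58, camera adjusted p = 0.0517). Tcf7, the transcription factor TCF-1 of naive T cells and thymocytes, rose (log2FC = 2.17, adjusted p = 6.3e-11), and Il7r, the IL-7 receptor alpha chain, fell (log2FC = -2.89, adjusted p = 1.27e-10). Of 9 helper T cell cytokines and regulators tested 3 rose and 2 fell (median log2FC = 0.32, camera adjusted p = 0.256), with Bcl6, a transcription factor of follicular helper T cells, at a log2FC of 0.69 (adjusted p = 8.19e-07). The counts of these lists were the same adjusted over the list alone.

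Genes of T cell receptor rearrangement, chosen after their values were seen, were abundant in the TNFR2-deficient libraries. Rag1, a subunit of the recombinase, was at 917.9 ± 72.7 CPM, rank 111 of the 17022 tested genes, against 3.31 ± 0.0785 CPM in the TNFR2-positive libraries (log2FC = 8.11, adjusted p = 1.78e-13). Rag2, the other subunit, was at 58.2 ± 1.03 against 0.193 ± 0.188 CPM (log2FC = 8.24, adjusted p = 9.22e-11). With 12 counts in the TNFR2-positive group its ratio was 311.5 (95% counting interval 178.1 to 603.3), and its log2FC was 7.60 without TNFR2-positive replicate 1 and 9.20 without TNFR2-positive replicate 3. Dntt, the terminal transferase that adds untemplated nucleotides at joins, was at 489.2 ± 9.95 against 2.05 ± 0.283 CPM (log2FC = 7.89, adjusted p = 1.78e-13). Trac itself was 1.48-fold higher, at 208.6 ± 3.95 against 141.1 ± 1.71 CPM (adjusted p = 3.24e-06), and the beta chain constant regions Trbc1 and Trbc2, whose near-identical sequences can share reads, were 4.10-fold and 3.71-fold higher (adjusted p = 1.15e-09 and 4.26e-10).

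Receptors and signals around TNFR2 and IL-2 were lower more often than higher. Some members also stand in the Treg core list, so these lists are not separate from it. They are Tnfrsf4, Tnfrsf9 and Tnfrsf18 of the TNF list, Il2ra and Socs2 of the IL-2 list, and Itgae of the trafficking list. Of 21 genes of the TNF and TNF receptor superfamily other than Tnfrsf1b, 12 fell and 8 rose (median log2FC = -0.60, camera adjusted p = 0.256). Tnfrsf9, the costimulatory receptor 4-1BB, fell (log2FC = -3.39, adjusted p = 1e-09), and Fas, the death receptor, rose (log2FC = 1.64, adjusted p = 3.3e-09). Of 25 NF-kB pathway genes 15 fell and 3 rose (median log2FC = -0.47, or -0.21 with the relation to gene length removed; camera adjusted p = 0.00328; adjusted p = 0.295 with an estimated correlation). Tnfaip3, a feedback inhibitor of NF-kB, fell (log2FC = -2.42, adjusted p = 1.77e-10), and Bcl2l1, the survival gene of BCL-xL, rose from 11.7 ± 0.708 to 74.9 ± 1.45 CPM (log2FC = 2.68, adjusted p = 6.44e-11). Of 14 IL-2 and STAT5 genes 9 fell and 2 rose (median log2FC = -0.75, camera adjusted p = 0.00639; adjusted p = 0.269 with an estimated correlation), Il2rb with a log2FC of -3.35 (adjusted p = 2.33e-11). Of 21 trafficking receptors tested 13 fell and 3 rose (median log2FC = -0.56, camera adjusted p = 0.0103; adjusted p = 0.295 with an estimated correlation). Itgae, the integrin CD103, fell (log2FC = -4.33, adjusted p = 5.53e-11), while Ccr9, a receptor of thymocytes and gut-homing T cells, rose (log2FC = 2.82, adjusted p = 1.81e-10). Of 16 apoptosis and p53 genes 7 rose and 5 fell (median log2FC = 0.02, camera adjusted p = 0.771), Bcl2l1 and Fas among the former. These counts were also the same adjusted over the list alone. Foxp3 at 1.44 against 75.5 CPM and Rag1 at 917.9 against 3.31 CPM moved with these groups.

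The tested genes of mitosis, DNA replication and the spindle checkpoint moved in both directions and by less than Trip13. In the DNA repair list Atm fell further. Of 27 mitosis genes 8 rose and 11 fell (median log2FC = -0.12, camera adjusted p = 0.443), and 0 of the 27 fell further than Trip13. The lowest was Kif20a, a kinesin of cytokinesis (log2FC = -1.15, adjusted p = 4.18e-06), and Top2a, a topoisomerase of dividing cells, fell by 0.91 on the log2 scale (adjusted p = 1.26e-06). Of 28 DNA replication and S phase genes 6 rose and 12 fell (median log2FC = -0.14, camera adjusted p = 0.196), with Mcm4 at -0.54 and Chaf1a at -0.93 (adjusted p = 7.85e-06 and 1.54e-05). Among 14 tested genes of the spindle checkpoint and of HORMA-domain partners of TRIP13, 6 rose and 5 fell (median log2FC = 0.02, camera adjusted p = 0.78). Mad1l1 and Mad2l1bp, which encodes the adaptor p31comet, rose by 1.63 and 0.92 on the log2 scale (adjusted p = 1.33e-08 and 1.52e-06). Of 18 DNA repair genes 4 rose and 11 fell, or 12 adjusted over the list alone (median log2FC = -0.49, camera adjusted p = 0.107). Xrcc6, which encodes the end-joining protein Ku70, rose (log2FC = 1.99, adjusted p = 1.81e-10), and Atm, the kinase of the double-strand break response, fell (log2FC = -3.91, adjusted p = 1.21e-07), with 7.99 ± 1.51 against 120.7 ± 47.8 CPM. The counts of the other 3 lists did not differ adjusted over the list alone. With the relation to gene length removed, the log2FC of Top2a, Chaf1a and Mad2l1bp were -0.52, -0.55 and 0.56. Rag1 and Dntt were higher in the same libraries (log2FC = 8.11 and 7.89).

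Of 15 acetyltransferase genes and partners besides Hat1, 10 fell and 3 rose (median log2FC = -0.40, camera adjusted p = 0.017; adjusted p = 0.337 with an estimated correlation). Ncoa3 and Kat7 fell by 1.30 and 0.66 on the log2 scale (adjusted p = 1.04e-07 and 2.81e-06). Of 17 deacetylases 11 rose and 4 fell (median log2FC = 0.42, camera adjusted p = 0.107), Hdac7, which is abundant in thymocytes, by a log2FC of 1.09 and Hdac4 by -1.39 (adjusted p = 2.71e-08 and 6.76e-08). Adjusted over the list alone, the counts were identical. Longer genes were lower in these libraries across all genes (rho = -0.298 between log2FC and exonic length), and with that relation removed the median of the acetyltransferases was -0.25 and the log2FC of Hdac4 -0.83. Foxp3 (log2FC = -5.71) and Rag1 (log2FC = 8.11) moved in the same libraries.

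Nuclear genes of oxidative phosphorylation were higher by a small amount. Of 30 tested 27 rose and 1 fell, or 28 and 1 adjusted over the list alone (median log2FC = 0.53, camera adjusted p = 3.65e-06; adjusted p = 0.40 with an estimated correlation). Ndufb3 and Ndufa1, subunits of complex I, rose by 0.78 and 0.77 on the log2 scale (adjusted p = 5.67e-06 and 5.84e-06). With the relation to gene length removed the median was 0.31, and 21 rose, with Ndufb3 and Ndufa1 at 0.44 and 0.37. In the same libraries Foxp3 was at 1.44 against 75.5 CPM, Rag1 at 917.9 against 3.31 CPM and globin genes at 1.89% against 0.592% of the counts. Mitochondrially encoded genes took 6.29% ± 0.127 of the counts against 5.0% ± 0.311. Of 18 glycolysis genes 5 rose and 5 fell (median log2FC = 0.04, mean -0.04, camera direction up, adjusted p = 0.988), with Slc2a3, the glucose transporter GLUT3, 1.91-fold lower and Slc16a1, a lactate transporter, 2.01-fold higher (adjusted p = 1.07e-07 and 3.09e-07). Of 16 cholesterol synthesis genes 10 fell and 3 rose (median log2FC = -0.34, camera adjusted p = 0.107). The counts for glycolysis and cholesterol synthesis held adjusted over the list alone.

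**Figure D2:**
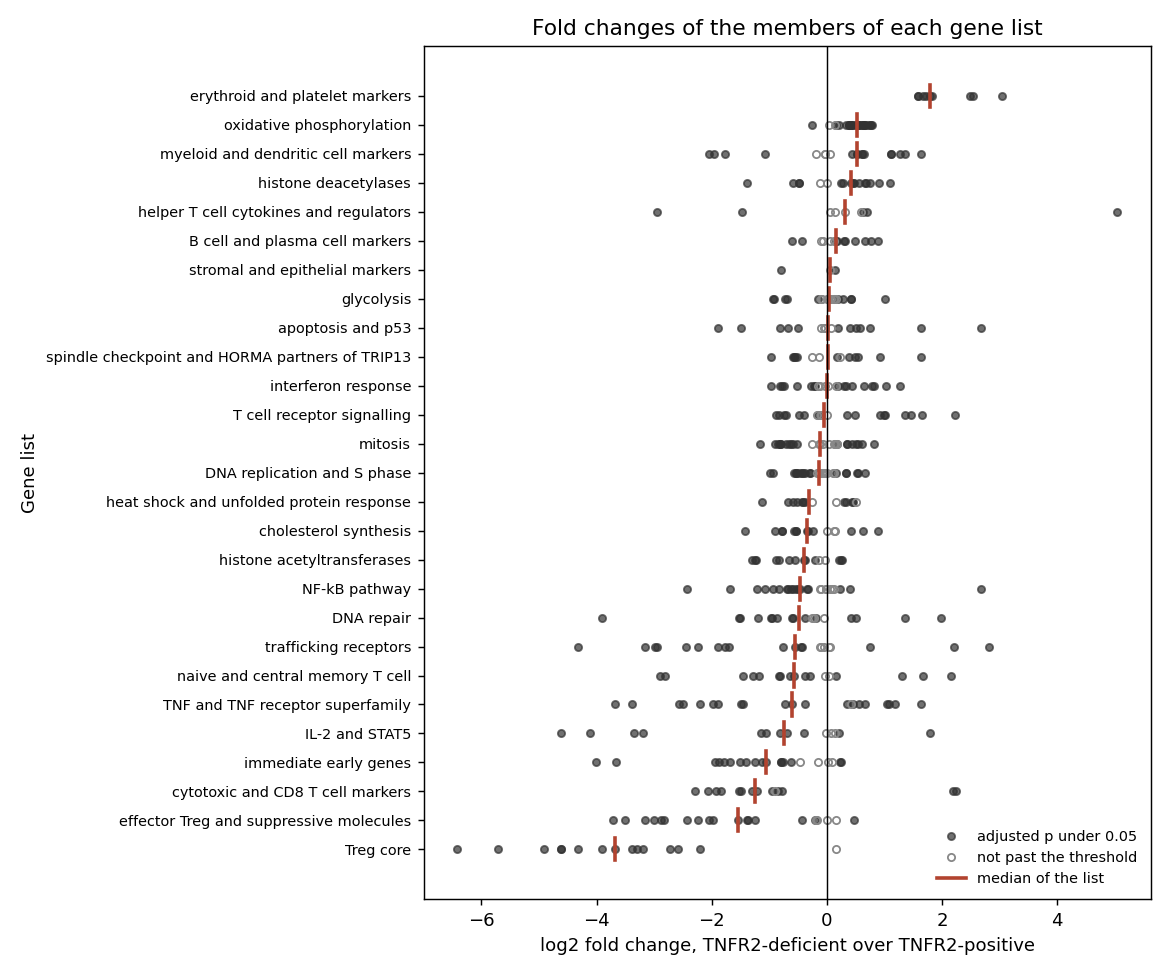
Log2 fold change (TNFR2-deficient over TNFR2-positive) of each tested member of the 27 gene lists, filled points past an adjusted p of 0.05 and open points not, with a red bar at each list's median. The Treg core list has the lowest median (-3.68) and the erythroid and platelet list the highest (1.80).

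Immediate early genes, which also respond to the handling of cells, were lower. Of 21 genes 15 fell and 2 rose, or 16 and 2 adjusted over the list alone (median log2FC = -1.05, camera adjusted p = 3.65e-06; adjusted p = 0.295 with an estimated correlation). The stress factor Atf3 fell by 3.66 and Klf6 by 1.95 on the log2 scale (adjusted p = 6.7e-10 and 1.05e-09). In the same libraries Foxp3 was at 1.44 against 75.5 CPM, Rag1 at 917.9 against 3.31 CPM and globin genes at 1.89% against 0.592% of the counts. Of 14 heat shock and unfolded protein response genes 4 rose and 7 fell, or 5 and 7 adjusted over the list alone (median log2FC = -0.32, camera adjusted p = 0.396), with the chaperones Hsph1 at -1.13 and Hsp90aa1 at -0.67 (adjusted p = 2.76e-08 and 2.17e-06). Of 22 interferon response genes 9 rose and 8 fell by both adjustments, including that adjusted over the list alone (median log2FC = -0.0038, mean 0.05, camera direction up, adjusted p = 0.988). Rsad2, the antiviral viperin, rose by 1.03 and Gbp2, a guanylate-binding protein, fell by 0.74 on the log2 scale (adjusted p = 5.14e-07 and 1.32e-06).

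Transcripts of other cell types were present in both groups. The 14 B cell and plasma cell markers took 1.86% ± 0.0444 of the counts in the TNFR2-deficient and 1.53% ± 0.0747 in the TNFR2-positive libraries, and 8 rose and 2 fell (median log2FC = 0.17, camera adjusted p = 0.126). Ighm, the IgM heavy chain, ranked 13 and 10 among the tested genes, at 5033 ± 132.5 and 4503 ± 272.1 CPM. Cd79a and Cd79b, the signalling chains of the B cell receptor, rose by 0.76 and 0.88 on the log2 scale (adjusted p = 3.27e-06 and 9.86e-07). All 9 erythroid and platelet markers rose (median log2FC = 1.80, camera adjusted p = 3.06e-05; adjusted p = 0.337 with an estimated correlation), among them Slc4a1, the anion exchanger of red cells, by 2.48 on the log2 scale (adjusted p = 1.27e-10). Globin genes, whose near-identical copies can share reads, took 1.89% ± 0.118 against 0.592% ± 0.155 of the counts. Of 19 myeloid and dendritic cell markers 11 rose and 4 fell (median log2FC = 0.52, camera adjusted p = 0.0787), with the macrophage genes Cd68 at 1.63 and Csf1r at 1.12 (adjusted p = 9.1e-09 and 1.49e-08). Of 3 stromal and epithelial markers tested 1 rose and 1 fell (median log2FC = 0.06, mean -0.20, camera direction up, adjusted p = 0.988), Pecam1 by 0.15 and Cdh5 by -0.79 (adjusted p = 0.033 and 0.0118). Both of these calls were lost with DESeq2 (adjusted p = 0.0548 and 0.0509; the highest over all alternatives were 0.137 and 0.0509), and that of Pecam1 also with other scalings and without most single libraries. Adjusted over the list alone, the counts of these lists did not change.

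Fold changes were related to gene length. Across 16643 genes with a known length, which are not independent replicates, Spearman's rho between log2FC and exonic length was -0.298. The median log2FC was 0.33 in the shortest and -0.57 in the longest of 10 equal groups of genes. Within the TNFR2-positive group, library 1 differed from libraries 2 and 3 in the opposite sense (rho = 0.339), and within the TNFR2-deficient group library 2 differed from libraries 1 and 3 with a rho of -0.187. Malat1, a long nuclear RNA chosen after its values were seen, was lower in the TNFR2-deficient libraries, at 371.3 ± 45.9 against 1717 ± 253.6 CPM (log2FC = -2.21, adjusted p = 1.66e-08). Of other nuclear RNAs chosen in the same way, Xist was at 465.5 ± 18.6 against 1130 ± 360.7 CPM (log2FC = -1.28, adjusted p = 2.7e-05) and Kcnq1ot1 at 12.9 ± 1.14 against 12.7 ± 0.802 CPM (log2FC = 0.03, adjusted p = 0.819). With the relation removed their log2FC were -0.71 and 1.76 (adjusted p = 1.09e-05 and 3.71e-07), and that of Malat1 was -1.53 (adjusted p = 1.45e-10). With the relation removed from each library, 11489 genes passed the threshold, of which 9775 were also called in the same direction without this step. The naive and central memory, TNF superfamily and DNA replication lists then passed camera in the lower direction (adjusted p = 0.0248, 0.0309 and 0.0309), though not with an estimated correlation (adjusted p = 0.151, 0.207 and 0.289). The medians of DNA repair, B cell, and myeloid and dendritic genes moved to -0.26, 0.06 and 0.21. Other genes named above whose log2FC moved by more than 1.5 times were Trac (0.18), Cd79a (0.42), Cd79b (0.55), Slc2a3 (-0.59) and Pecam1 (0.40).

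**Figure D3:**
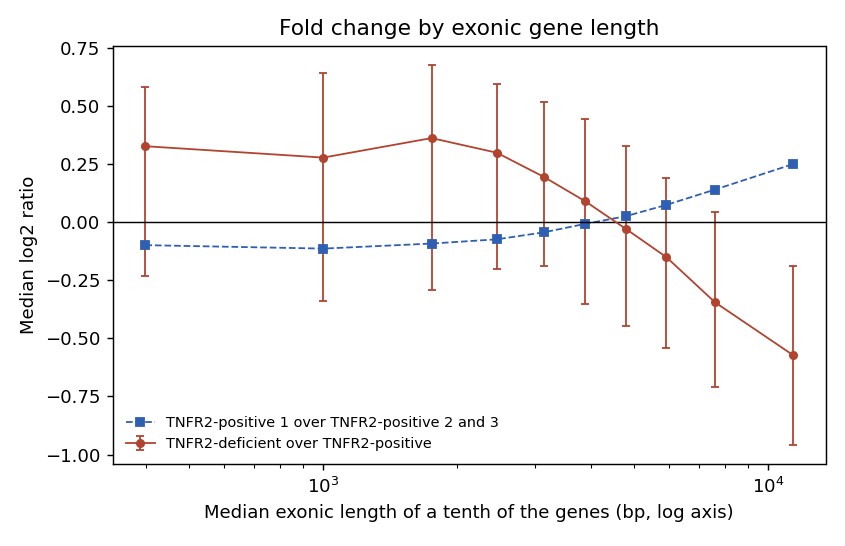
Median log2 ratio in 10 equal groups of genes ordered by exonic length, plotted at each group's median length in base pairs on a log axis. Red points compare TNFR2-deficient with TNFR2-positive libraries, with bars from the lower to the upper quartile of genes, and fall from 0.33 to -0.57, while blue squares compare TNFR2-positive library 1 with libraries 2 and 3 and rise from -0.10 to 0.25.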

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

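The alternatives that remove the relation to gene length or leave out abundant genes of other cells were chosen after the data were seen. Over the alternatives other than a minimum fold, 10771 to 13273 genes were called, and 46.4% to 56% of them were higher in the TNFR2-deficient libraries. A minimum log2 fold change of 1 left 1364 higher and 2299 lower genes, fewer by its own construction. Tnfrsf1b and Trip13 kept their direction and call throughout (leave-one-out log2FC -3.44 to -3.36 and -2.40 to -2.14). Hat1 ranged from 0.169 to 0.311 with single libraries left out and missed the threshold without TNFR2-deficient replicate 1 (0.2027, adjusted p = 0.0775), where fewer libraries were tested. With the replicate block 11856 genes were called, of which 11674 were shared with the fit without it, and it ended no call of a gene or list named here. Whether replicate numbers pair the libraries is not given by the labels, and the counts do not settle it. With each gene's group mean removed, same-numbered libraries of the 2 groups correlated at 0.0372, 0.054 and -0.0611. Libraries with different numbers correlated at -0.109 to 0.0762, TNFR2-deficient library 2 with TNFR2-positive library 3 at 0.0728. With 3 libraries per group, such values neither show nor exclude a pairing. Of the named genes and markers, 14 results missed the threshold under an alternative, for Hat1, Alb, Pecam1, Cdh5 and Bst1, and Kcnq1ot1 passed with the length relation removed (log2FC = 1.76, adjusted p = 3.71e-07, against 0.03 and 0.819). No called gene named here reversed, but of 9976 genes called with and without the length removal only 9775 kept their direction. Kcnq1ot1 and Ccl25, not called, changed sign in some. Of the list calls, 10 were lost with an estimated correlation, while fry added 12, the length removal 4 (none with an estimated correlation) and leaving out a library 2. At 19296082 to 24038118 counts per library, depth limits folds of genes with few counts in one group, such as Syt13 and Ptcra.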

Other observations

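The tests on thymocyte genes and on Treg core genes below, the test of gene length within the TNFR2-deficient group and the count of oxidative phosphorylation genes after length removal were chosen only after the result was seen; the other tests on gene length and the splits were written before.

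Some single genes known from macrophages, picked because they were high, were higher in the TNFR2-deficient libraries, while the myeloid and dendritic list as a whole was not past the threshold (camera adjusted p = 0.0787; adjusted p = 0.502 with an estimated correlation). Hmox1, the heme-degrading enzyme, was at 199.4 ± 5.69 against 49.2 ± 3.93 CPM (log2FC = 2.02, edgeR adjusted p = 7.2e-10, n = 3 per group). Slc40a1, the iron exporter ferroportin, was at 235.9 ± 1.15 against 71.2 ± 3.37 CPM (log2FC = 1.73, adjusted p = 7.19e-10), and Vcam1 at 324.9 ± 19 against 101.0 ± 7.31 CPM (log2FC = 1.68, adjusted p = 3.66e-09). The complement genes C1qa, C1qb and C1qc rose by 2.56, 2.56 and 2.71 on the log2 scale, Axl by 1.48 and Apoe, a lipid carrier, by 1.81. Of the same list, Clec9a, Xcr1 and Siglech, also picked after their values were seen, had log2FC of -2.04, -1.96 and -1.76 (adjusted p = 1.24e-06, 3.68e-05 and 8.07e-07), while H2-Aa, H2-Ab1 and H2-Eb1 rose by 0.52, 0.52 and 0.61. Eomes and Ncr1 of the cytotoxic list, picked likewise, fell by 2.28 and 2.07 on the log2 scale (adjusted p = 1.87e-08 and 9.35e-08).

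Genes of CD4 and CD8 double-positive thymocytes were higher in every TNFR2-deficient library, with 16 of 16 listed markers called higher, of which 10 had been seen before listing and 6 are also in lists fixed earlier, and Rag1, Satb1 and Cd8a the most abundant at 917.9, 873.5 and 686.9 CPM. RNA of double-positive thymocytes in these libraries is a candidate explanation: of the 6 markers whose values had not been seen, all 6 were called higher, namely Ptcra, Cd1d1, Themis, Tox, Myb and Ets2 (log2FC of the last 5 0.66, 2.31, 0.54, 2.82 and 2.34; Ptcra 1 count in the TNFR2-positive group, ratio 364.1, 95% counting interval 64.97 to 14420, with the fitted log2FC of 8.07 rising to 10.02 without TNFR2-positive replicate 2, which held that count). These 6 markers were listed after other genes of the same cells, such as Rag1, had been seen to be high. They are therefore no independent test. Of all 17022 tested genes, 5983 were called higher. B cell precursors, which also use Rag1, are argued against as its main source, since Igll1 plus Vpreb1 reached 0.0501% of the Rag1 level. Vpreb2 was at 0.0426 CPM, Vpreb3 at 41.4, Cd93 at 9.74 and Bst1 at 3.0 in the TNFR2-deficient libraries. Against the TNFR2-positive libraries, Vpreb3 was higher (log2FC = 0.72, edgeR adjusted p = 8.24e-06), while Cd93 and Bst1 were lower (log2FC = -1.22 and -0.46). Vpreb1 had a ratio of 4.63 (95% counting interval 1.90 to 13.61), with 6 counts in the TNFR2-positive group. The thymic epithelial genes Foxn1, Psmb11, Prss16 and Ccl25 were at 0.0144, 0.113, 1.53 and 4.93 CPM in the TNFR2-deficient libraries. What stays open is whether thymocytes entered with the cells or the tissue taken differed, since the labels name neither a tissue nor a sort that would remove them.

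Of 15 Treg core genes, 14 were lower in every TNFR2-deficient library, Capg being the exception. A smaller share of Treg cells with the mix of all other cells kept would raise the B cell and the erythroid and platelet lists alike. The median of the erythroid and platelet list exceeded that of the B cell list by 1.63 on the log2 scale. Both medians were known when this comparison was written, so it describes these libraries and is no test. It speaks only to an unchanged mix of these markers, not to a smaller share of Treg cells as such. A smaller share of Treg cells with a changed mix of other cells may underlie the fall. Foxp3, Ctla4, Il2ra, Lrrc32 and Gpr83, picked after the values were seen, each had a log2FC of -4.617 or lower. They are the members of the list that fell furthest. Falls of other members were smaller, as with Tnfrsf4 (log2FC = -2.21) and Nrp1 (log2FC = -2.59), so the fall was not uniform. Lower expression per Treg cell without TNFR2 cannot be told apart from a smaller share of these cells. Foxp3 at 0.692% of Trac would follow from either, and the counts hold no share of cells. The effect of TNFR2 deficiency on Treg cells, on Trip13 and on Hat1 stays open for the same reason. So does whether the fall of Tnfrsf1b came from a loss of TNFR2 within Treg cells or from a smaller share of them.

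Longer genes were lower and shorter ones higher in the TNFR2-deficient libraries. Whether differences between libraries in unspliced or nuclear RNA contribute stays open. TNFR2-positive library 1 had the most Malat1 of its group. It exceeded libraries 2 and 3 by more in genes with longer introns (rho = 0.271 across genes). TNFR2-deficient library 2, with the most Malat1 of its group, went the other way (rho = -0.152). Between the groups the relation was weaker for intronic than for exonic length (rho = -0.203 and -0.298). The same held for TNFR2-positive library 1 against libraries 2 and 3 (rho = 0.271 and 0.339). The weaker intronic relation therefore does not set the 2 comparisons apart. The length relation as the whole source of the called genes is argued against, as 11489 genes passed after its removal. After the removal, 21 of 30 oxidative phosphorylation genes were still called higher. This speaks against the removed relation as the whole source of their rise. That criterion was written after the count was seen, so it is no independent test. The list then gave a camera adjusted p of 0.00108, but 0.575 with an estimated correlation. The median of 0.314 after removal, from 0.528, lies between the bounds set in advance. How much of the rise length contributes therefore cannot be told apart from the rest. A different mix of cells, as above, is an open alternative that was not tested against length.

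Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many higher and 1 as many lower genes as the real split, which was the real one each time with 5983 and 5819 genes. The highest of the other splits was 0 with edgeR, and 31 genes in one direction at an unadjusted p-value below 0.05. Each other split put libraries of both groups on both sides, so the difference between the groups counted as spread within a side. Few calls had to follow there, and these splits give no measure of what unrelated libraries would yield. With 10 splits the share cannot be under 0.1, too few for a share under 0.05.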
